A study of Mus musculus with 6 samples.

How the data were processed

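Brain tissue was taken from mice at 3 and 28 days after implantation of MCF10DCIS cells, a human line used as a model of ductal carcinoma in situ, an early breast lesion. The cells carried CD63, a membrane protein of extracellular vesicles, fused to the light-producing enzyme NanoLuc. Each time point had 3 libraries. Per the labels' protocols, total RNA was extracted from homogenized brain with TRIzol and a column kit, polyadenylated RNA was selected, and stranded libraries were made from 1 µg of RNA and pooled for sequencing. No library of an unimplanted mouse was used here. The labels do not state that the libraries of a group came from separate animals, so p-values measure the spread between these samples, which may in part be technical.

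The deposited table held log2 values for 56748 mouse genes in 6 libraries. Per the submitters' processing notes the genome build was GRCm39. The aligner, the counting tool, the annotation and the scaling tool were not given in the sources used here. Undoing the log2 and the added 1 gave whole multiples of 1 step per library for 100% of values, within a tolerance of 0.001 reads. The deposited log2 values are therefore read counts divided by a size factor, plus 1, on a log2 scale. The recovered size factors ran from 0.822 to 1.12 and equalled median-of-ratios factors recomputed from the recovered reads. Recovered totals ran from 11958137 to 16059196 reads per library. Gene symbols came from GENCODE M21 names, which matched 52073 of the table's identifiers and 15978 of the 16162 tested. That release belongs to an older build, so no coordinates are given.

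The deposited unit was log2, so the comparison used limma 3.58.1 in R 4.3.3 on log2(normalized count + 1) and no count model. Genes with a mean normalized count of at least 10 over the 6 libraries were tested. This kept 16162 genes, which held 99.77% to 99.84% of the reads of a library. Group was the only term, with an intensity trend in the variance prior and 4 residual degrees of freedom. Tests were two-sided with Benjamini-Hochberg adjustment at 0.05. A fold change is on the log2(value + 1) scale, which understates changes of low genes. Where a group had 0 reads in every library, a bound was computed from a floor of 3 reads over the group, which covers counting error only.

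Before the data were examined, 45 gene lists were fixed for brain cell types and regions, activity, stress, immunity, barrier, vesicles and RNA quality. Of these, 42 had at least 5 tested members. Each was tested with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. Lists share genes. Named genes followed a rule also fixed then. It took the 10 largest rises and falls among genes past the threshold whose groups did not overlap, and up to 4 members of smallest p in each list that passed and in 5 lists named in advance. It also took up to 3 members per list past the threshold, and Cd63. Other genes named were chosen after their values were seen.

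The procedure was tested on simulated data with the real genes and depths. Of the genes changed 2-fold, 74.2% were called, against 91.5% at 4-fold and 98.9% at 8-fold. Over 10 runs of 16162 genes, 74 of 159420 unchanged genes were called. The simulated spread was smoothed over genes of like level, and no library had a shift of its own. These shares therefore do not hold for genes that vary more than others of their level. Among real genes, Slc6a5 had a log2 difference of -7.26 and was not called (limma adjusted p = 0.0507). A raised list was found in 10 of 10 runs and 0 of 420 unchanged lists were called. Simulated genes varied independently and the unchanged lists were random genes. That result therefore does not show how often camera calls unchanged lists of correlated genes. Estimated correlations in the real lists reached 0.82, for interferon-stimulated genes. Libraries of 1 group differed far beyond sampling noise, with a chi-square per degree of freedom of at least 8.93, so each was counted as 1 sample.

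Alternatives covered the pseudocount, the filter, the scaling, the variance model, library weights, a block on the replicate number, the threshold, the list test and leaving out each library. After the data were seen, voom on the recovered reads, a covariate for cerebellar genes and the removal of 2 libraries rich in cerebellar transcripts were added. Figures were drawn with matplotlib 3.10.9.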

Results

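Polyadenylated RNA was sequenced from brain tissue of mice implanted with MCF10DCIS cells that carry NanoLuc-labelled CD63. The series asked how brain gene expression differed between 3 and 28 days after implantation, with 3 libraries at each time. Depth was 15033955, 14081027 and 11958137 reads for day 3 replicates 1 to 3 and 14230520, 16059196 and 14958700 reads for day 28. All folds are day 28 relative to day 3, from limma with adjusted p, and values are normalized counts as mean ± SD with n = 3 per group.

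The monoamine transporter genes Slc6a3 and Slc18a2 and 6 of 18 glucocorticoid-responsive genes fell at day 28, and single striatal and activity-linked genes rose. The transporter falls may come from a different share of brain regions in the tissue, as described below. Slc6a3, the dopamine transporter, fell from 187 ± 3.46 to 2.87 ± 1.10 normalized counts (log2 fold change -5.64, SE 0.40, adjusted p = 0.00405). Plin4, a lipid droplet coat protein, fell from 217 ± 55.4 to 17.3 ± 2.25 (log2 -3.55, SE 0.28, adjusted p = 0.00562). Rgs9, a regulator of G protein signalling enriched in striatum, rose from 957 ± 81.4 to 1991 ± 404 (log2 1.04, SE 0.15, adjusted p = 0.0411). In all, 31 of 16162 genes changed, 11 higher and 20 lower at day 28, and the groups did not overlap for any of the 31. Among all tested genes, 18.9% had groups that did not overlap, against 10% by chance.

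The count depended on single libraries. It was 2 without day 3 replicate 2, 623 without day 3 replicate 3, 1 without day 28 replicate 1 and 2 without day 28 replicate 2 or replicate 3, while without day 3 replicate 1 it was again 31, of which 16 were shared; it was 0 with voom, 16 with voom on total reads as library size, and 2 with a covariate for cerebellar genes.

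**Figure D1:**
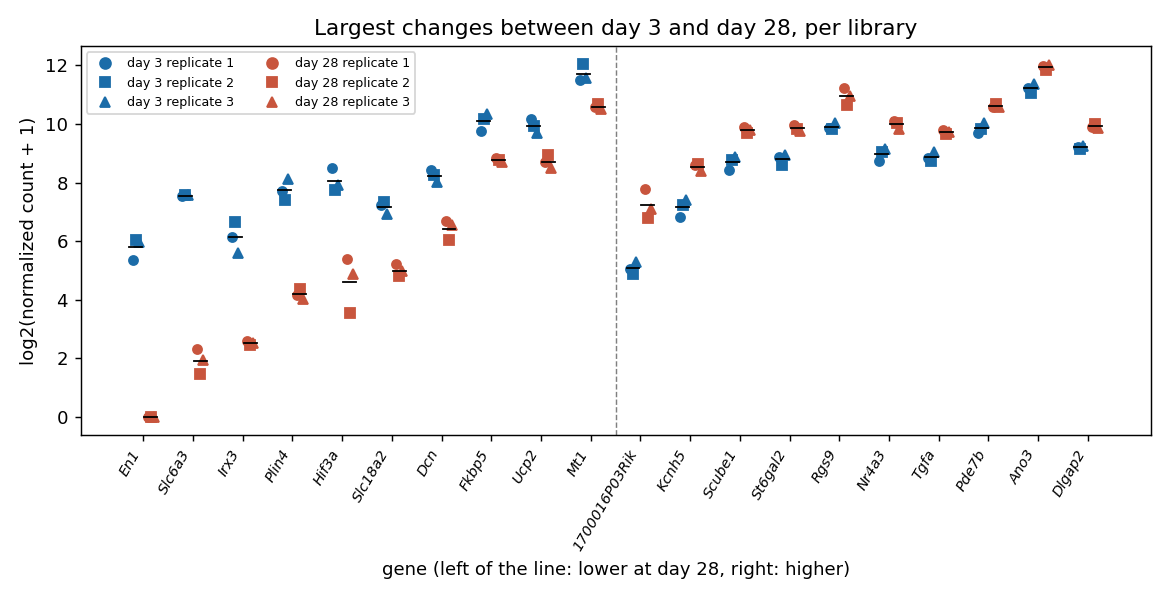
Values per library, as log2(normalized count + 1), of the 10 genes with the largest falls and the 10 with the largest rises past the threshold. Points are libraries, blue for day 3 and red for day 28, and black bars are group means; En1 lay at 0 in all 3 day 28 libraries.

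Slc6a3, Slc18a2, En1 and Irx3 were among the 10 largest falls past the threshold. Of 24 transcription factors of the midbrain and hindbrain, 23 were also lower, as a different share of brain regions in the tissue predicts. These falls therefore do not show a change of expression within cells. En1, a homeobox gene of the midbrain and hindbrain, had 55.7 ± 13.4 normalized counts at day 3 and 0 reads in each day 28 library, so it was at least 59.0-fold lower. Slc18a2, the vesicular monoamine transporter, fell by 2.17 on the log2 scale (SE 0.26, adjusted p = 0.0345), and Irx3, another homeobox gene, fell by 3.61 (SE 0.47, adjusted p = 0.0345). Ddc, which makes dopamine and serotonin, had a log2 difference of -1.64 that did not pass (adjusted p = 0.0838). The list of thalamic and midbrain neuron genes was lower (median log2 -0.13, adjusted p = 0.00316 with camera; adjusted p = 0.483 with an estimated correlation). Of its 19 members, 2 fell over all genes tested and 3 adjusted over the list alone. The median log2 fold change of thalamic and midbrain neuron genes ran from -0.46 without day 28 replicate 3 to 0.08 without day 28 replicate 1 (adjusted p = 0.55), and the list did not pass without day 3 replicate 3 either (adjusted p = 0.0659).

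Hindbrain and cerebellar genes were lower as lists but uneven between libraries. The 12 hindbrain and spinal motor genes had a median log2 difference of -3.09 (adjusted p = 1.92e-06; adjusted p = 0.384 with an estimated correlation), with 0 members past the threshold over all genes and 7 lower adjusted over the list alone. Without day 3 replicate 1, the median log2 fold change of hindbrain and spinal motor genes was -1.81. Slc6a5, the neuronal glycine transporter, stood at 483 ± 420 and 2.21 ± 3.83 normalized counts (adjusted p = 0.0507). The 19 cerebellar neuron genes had a median of -1.95 (adjusted p = 5.46e-07; adjusted p = 0.439 with an estimated correlation), with 0 members over all genes and 1 lower adjusted over the list alone. Their mean deviations were 2.48, 2.41 and -1.49 in day 3 replicates 1 to 3 and -1.81, -1.86 and 0.26 at day 28. Without day 3 replicate 3 the median log2 fold change of cerebellar neuron genes was -3.06. Gabra6, a granule cell receptor subunit, had 2295, 2117 and 0 reads at day 3 and 0, 0 and 211 at day 28.

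The glucocorticoid-responsive list was lower at day 28, with a median of -0.999 (adjusted p = 6.24e-12; adjusted p = 0.306 with an estimated correlation). Of 18 members, 6 fell over all genes tested, while 11 were lower and 1 higher adjusted over the list alone. The 6 were Plin4, Hif3a (log2 -3.44), Fkbp5 (log2 -1.32, SE 0.15, adjusted p = 0.0345), Mt1 (log2 -1.12), Zbtb16 (log2 -1.06) and Tsc22d3 (log2 -0.93). Fkbp5 encodes a co-chaperone of the glucocorticoid receptor and Tsc22d3 a glucocorticoid-induced leucine zipper protein. Mt1 has close relatives, and reads shared with them make its value uncertain. Among the 12 that did not pass, Per1 (log2 0.34) and Ddit4 (log2 0.03) had positive differences. Mean deviations of the list were 0.46, 0.88 and 0.48 at day 3 and -0.51, -0.77 and -0.54 at day 28. Day 3 replicate 2 also held 65795 reads of Alb, the liver-made albumin, against 23 to 1276 in the other libraries.

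Immediate early genes, which neurons switch on with activity, were higher as a list at day 28. Their median was 1.03 over 22 members (adjusted p = 3.93e-17; adjusted p = 0.372 with an estimated correlation), with 1 risen over all genes and 18 adjusted over the list alone. Mean deviations were -1.07, -0.37 and -0.16 at day 3, lowest in replicate 1, and 0.58, 0.78 and 0.24 at day 28. The striatal list (median 0.71) and the list of long transcripts, a sign of RNA integrity (median 0.23), were also higher (for these, adjusted p = 0.372 and 0.483 with an estimated correlation). The long transcripts had mean deviations of 0.20, -0.35 and -0.17 at day 3 and 0.06, 0.02 and 0.24 at day 28. They went against the immediate early genes in day 3 replicate 1 alone and had the same sign in every other library. Whether RNA integrity or a different share of brain regions had a part in the rise was not tested. Nr4a3, an orphan nuclear receptor, rose from 503 ± 70.0 to 1014 ± 93.0 (log2 1.01, adjusted p = 0.0345). Fos had a log2 difference of 1.68 (adjusted p = 0.0666), Npas4 of 2.01 (adjusted p = 0.0786) and Fosb of 1.79 (adjusted p = 0.083), none of which passed.

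**Figure D2:**
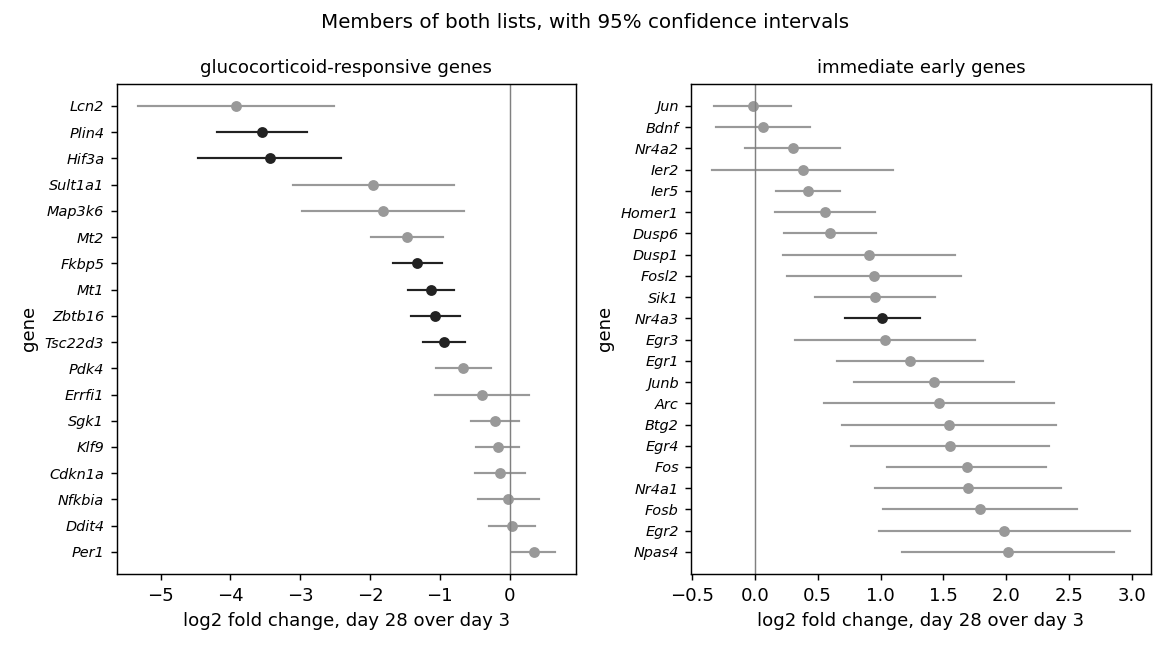
Log2 fold change, day 28 over day 3, of each tested member of the glucocorticoid-responsive and immediate early lists, with 95% confidence intervals that are not adjusted for multiple tests. Black marks genes past the adjusted threshold over all genes, 6 in the first list and 1 in the second.

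Striatal genes and some other forebrain lists were higher, but whether a different share of brain regions gave these rises was not tested. The 19 striatal medium spiny neuron genes had a median of 0.71 (adjusted p = 3.93e-17; adjusted p = 0.372 with an estimated correlation), with 1 risen over all genes, Rgs9, and 17 adjusted over the list alone. Mean deviations of the striatal list were -0.68, -0.45 and -0.05 at day 3 and 0.59, 0.26 and 0.33 at day 28. They were lowest in day 3 replicates 1 and 2, the libraries rich in cerebellar transcripts. Pde10a, a striatal phosphodiesterase, stood at 3391 ± 528 and 6235 ± 795 (adjusted p = 0.0516). Olfactory bulb and neuroblast genes had a median of 0.87 (adjusted p = 1.40e-08; adjusted p = 0.384 with an estimated correlation), with 0 of 18 over all genes and 10 higher adjusted over the list alone. Their mean deviations were -0.90, -0.80 and -0.13 at day 3 and 1.23, 0.61 and -0.01 at day 28, so that day 28 replicate 3 lay near day 3 replicate 3. Dcx, a protein of migrating neuroblasts, had a log2 difference of 1.69 (adjusted p = 0.122). Inhibitory neuron markers had a median of 0.37 and synaptic genes of 0.25 (adjusted p = 0.00158 and 1.88e-06; for both, adjusted p = 0.384 with an estimated correlation), with 0 members past the threshold over all genes. Without day 3 replicate 1 the median log2 fold change of inhibitory neuron markers was 0.18 (adjusted p = 0.0638) and the median log2 fold change of synaptic genes 0.16. Adjusted over the list alone, 6 inhibitory markers were higher and 1 lower, and 1 synaptic gene was higher. The lower inhibitory marker was Pvalb, which is also in the cerebellar list. Excitatory forebrain neuron markers had a median of 0.32 (adjusted p = 0.00248; adjusted p = 0.483 with an estimated correlation), with 0 of 19 past the threshold over all genes, and 5 higher and 3 lower adjusted over the list alone. The 3 lower were Neurod1, Neurod2 and Nptx1. Neurod1 is also in the cerebellar list, with log2 values of 10.74, 10.63 and 8.02 at day 3 and 7.18, 7.79 and 8.57 at day 28. The median log2 fold change of excitatory forebrain neuron markers was 0.13 without day 3 replicate 1 (adjusted p = 0.0926) and 0.49 without day 3 replicate 3. Hippocampal neuron genes did not pass (median -0.20 over 16 members, adjusted p = 0.242). A list of long transcripts, fixed as a sign of RNA integrity, was also higher, with a median of 0.23 close to that of the synaptic genes (adjusted p = 3.82e-05; adjusted p = 0.483 with an estimated correlation). Of its 20 members 19 had a positive difference, 0 passed over all genes and 1 was higher adjusted over the list alone. With single libraries left out, the median log2 fold change of long transcripts (over-long genes sensitive to RNA integrity) was 0.39 without day 3 replicate 1 and 0.10 without day 3 replicate 2. Other genes that rose were Kcnh5, a potassium channel (log2 1.39), Scube1 (log2 1.10), St6gal2 (log2 1.05), Tgfa, a growth factor (log2 0.85), Pde7b (log2 0.77), Ano3 (log2 0.72) and Dlgap2, a postsynaptic scaffold (log2 0.72). The largest rise was that of the unnamed transcript 1700016P03Rik (log2 2.15).

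Of the glial lists, those of myelin, astrocyte, reactive astrocyte and disease-associated microglia genes were lower, and those of microglia markers and oligodendrocyte precursors did not pass. Myelin genes had a median of -0.45 over 20 members (adjusted p = 1.09e-11; adjusted p = 0.372 with an estimated correlation), with 0 past the threshold over all genes and 13 lower adjusted over the list alone, among them Mobp (log2 -0.63) and Cldn11 (log2 -0.67). Whether a different share of brain regions had a part in the myelin fall was not tested. Among 18 astrocyte markers Aldoc, a glycolytic enzyme, fell by 0.68 (adjusted p = 0.0345). The list median was -0.28 (adjusted p = 3.87e-05; adjusted p = 0.372 with an estimated correlation), with 5 lower and 1 higher adjusted over the list alone. Reactive astrocyte genes had a median of -1.11 (adjusted p = 4.22e-06; adjusted p = 0.372 with an estimated correlation), with 0 of 17 over all genes and 2 lower adjusted over the list alone. Their mean deviations were 1.41, 0.86 and -0.35 at day 3 and -0.74, -0.53 and -0.65 at day 28, highest in day 3 replicate 1, and without that library the median log2 fold change of reactive astrocyte genes was -0.66. Lcn2 stood at 135 ± 88.1 and 6.89 ± 3.26 normalized counts (adjusted p = 0.0548). The 18 disease-associated microglia genes had a median of -0.33 (adjusted p = 0.000903; adjusted p = 0.384 with an estimated correlation), with 0 past the threshold over all genes and 3 lower and 1 higher adjusted over the list alone. Without day 3 replicate 1 the median log2 fold change of disease-associated microglia genes was -0.25 (adjusted p = 0.0638). The 18 oligodendrocyte precursor and newly formed oligodendrocyte genes had a median of -0.06 (adjusted p = 0.245). The 20 microglia markers did not pass as a list (median -0.21, adjusted p = 0.352), with 0 members past the threshold over all genes or adjusted over the list alone.

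Interferon-stimulated genes were on average highest in day 3 replicate 1, and several were also high in day 3 replicate 2. The 24 members had mean deviations of 2.64, 0.20 and -0.84 at day 3 and -0.55, -0.81 and -0.64 at day 28. The list median was -1.24 (adjusted p = 3.46e-06; adjusted p = 0.483 with an estimated correlation), with 0 members past the threshold over all genes or adjusted over the list alone. The median log2 fold change of interferon-stimulated genes was -0.26 without day 3 replicate 1 (adjusted p = 0.146) and -2.15 without day 3 replicate 3. B2m, the light chain of class I molecules, stood at 2373 ± 2068 and 488 ± 49.1 normalized counts (adjusted p = 0.259), with log2 values of 12.17, 10.96 and 9.04 at day 3 and 9.05, 8.76 and 8.98 at day 28.

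**Figure D3:**
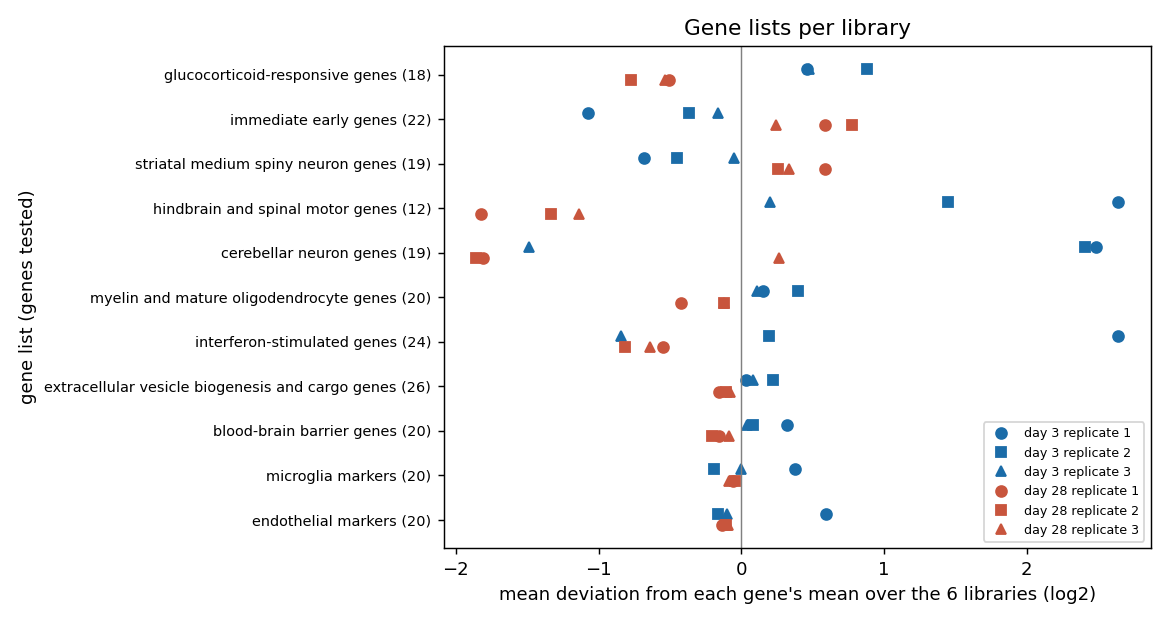
Mean deviation, in log2, of the members of 11 gene lists from each gene's mean over the 6 libraries. Each point is a library, blue for day 3 and red for day 28. The interferon list stands at 2.64 in day 3 replicate 1. The glucocorticoid list separates the days, as do the immediate early, striatal, hindbrain, myelin, vesicle and barrier lists.

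The barrier, fibroblast and vesicle lists were lower, and the 20 endothelial markers did not pass (median -0.14, adjusted p = 0.128). Slc2a1, the glucose transporter of the blood-brain barrier, fell by 0.74 (SE 0.09, adjusted p = 0.0345). The 20 barrier genes had a median of -0.25 (adjusted p = 0.00175; adjusted p = 0.306 with an estimated correlation), with 1 fallen over all genes and 4 lower adjusted over the list alone, among them Mfsd2a (log2 -1.04) and Lsr (log2 -1.19). Lsr was highest in day 3 replicate 2, the library high in Alb, with log2 values of 6.77, 7.74 and 6.84 at day 3. At day 28 they were 6.15, 5.86 and 5.76. The median log2 fold change of blood-brain barrier genes was -0.12 without day 3 replicate 1 (adjusted p = 0.0926). Among fibroblast genes Dcn, a matrix proteoglycan, fell by 1.81 (SE 0.22, adjusted p = 0.0345). The 20 meningeal and vascular fibroblast genes had a median of -0.51 (adjusted p = 0.00137; adjusted p = 0.384 with an estimated correlation), with 1 fallen over all genes and 1 adjusted over the list alone. Leaving out day 3 replicate 2, the median log2 fold change of meningeal and vascular fibroblast genes was -0.32. Ucp2, a mitochondrial carrier, fell by 1.22 (SE 0.16, adjusted p = 0.0345). The 26 extracellular vesicle genes had a median of -0.13 (adjusted p = 0.000569; adjusted p = 0.384 with an estimated correlation), with 0 past the threshold over all genes and 3 lower adjusted over the list alone. Cd81, a tetraspanin of vesicles, stood at 5375 ± 70.7 and 3791 ± 225 normalized counts (adjusted p = 0.0573). Mouse Cd63 stood at 568 ± 29.7 and 466 ± 22.0 (log2 -0.29, adjusted p = 0.293) and did not pass.

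Further lists passed with small medians or unevenly between libraries. Nuclear-encoded oxidative phosphorylation genes had a median of -0.17 (adjusted p = 3.49e-05; adjusted p = 0.508 with an estimated correlation), with 0 of 30 past the threshold over all genes or adjusted over the list alone. Without day 3 replicate 2 the median log2 fold change of nuclear-encoded oxidative phosphorylation genes was -0.08 (adjusted p = 0.0504), and without day 3 replicate 1 it was -0.31. Heat shock and unfolded protein response genes had a median of -0.22 (adjusted p = 0.000433; adjusted p = 0.508 with an estimated correlation), with 0 of 23 over all genes and 4 lower adjusted over the list alone, and the median log2 fold change of heat shock and unfolded protein response genes was -0.14 without day 3 replicate 3 (adjusted p = 0.0508) and -0.39 without day 3 replicate 1. Insulin, feeding and hypoxia genes had a median of -0.17 (adjusted p = 0.00137; adjusted p = 0.306 with an estimated correlation), with 2 of 19 fallen over all genes, Slc2a1 and Hif3a, and 3 lower adjusted over the list alone; the median log2 fold change of insulin, feeding and hypoxia genes was -0.26 without day 3 replicate 1 and -0.11 without day 3 replicate 2. Neurogenesis and developmental genes had a median of 0.35 (adjusted p = 0.00311; adjusted p = 0.483 with an estimated correlation), with 0 of 19 over all genes and 3 higher adjusted over the list alone. Leaving out day 3 replicate 1, the median log2 fold change of neurogenesis and developmental genes was 0.21 (adjusted p = 0.166), and it was also 0.21 without day 28 replicate 1. The 5 neutrophil and monocyte genes had a median of -1.26 (adjusted p = 0.0478; adjusted p = 0.384 with an estimated correlation), with 0 past the threshold over all genes or adjusted over the list alone. Leaving out day 3 replicate 1, the median log2 fold change of neutrophil and monocyte genes was -0.34 (adjusted p = 0.386), and the list did not pass without day 28 replicate 1, 2 or 3 (adjusted p = 0.0713, 0.0555 and 0.0575).

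Of the 42 lists tested, 26 passed with the preset correlation, 8 higher and 18 lower. With an estimated correlation 0 passed, with 4 at an unadjusted p under 0.05, and with fry 0 passed for movement in 1 direction (smallest adjusted p = 0.101) and 19 for change in either direction.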

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

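All alternatives to the number of genes changed (31, with 11 higher and 20 lower) were planned, except voom, the cerebellar covariate and the removal of day 3 replicates 1 and 2, which were chosen after seeing the data. The 31 genes kept their sign under every alternative that tested them. The count was 68 (30 higher, 38 lower) with no filter on low values, 74 (37 and 37) with a robust prior, 69 (29 and 40) with array weights, and 152 (81 and 71) at adjusted p under 0.1. It was 19 (6 and 13) with an absolute log2 fold of at least 1, 3 (0 and 3) with no trend and 2 (0 and 2) with the cerebellar covariate. Limma called 0 genes (0 and 0) with both cerebellum-rich day 3 libraries left out, with 1904 at an unadjusted p under 0.05. Voom on recovered reads called 0 (0 and 0), with 2113 at that p, and 16 (7 and 9) with total reads as library size. Both voom settings are given since they differ only in the scaling. Leaving out 1 library gave 1 to 623 genes, 0 to 325 higher and 1 to 298 lower. With upper-quartile scaling 32 genes were called, 14 higher and 18 lower; the cause of these shifts was not tested. The number of lists was 26 (8 higher, 18 lower), 20 to 27 over the libraries left out, and 0 with an estimated correlation. With the cerebellar covariate it was 21 (5 higher, 16 lower). Leaving out both cerebellum-rich day 3 libraries leaves at day 3 the 1 library low in cerebellar transcripts. The medians of 4 of the 26 lists that had passed then changed sign. The median log2 fold change of interferon-stimulated genes was 0.0474 (adjusted p = 0.687), the median log2 fold change of excitatory forebrain neuron markers -0.0292 (adjusted p = 0.959), the median log2 fold change of cerebellar neuron genes 0.36 (adjusted p = 0.128) and the median log2 fold change of neutrophil and monocyte genes 0.0221 (adjusted p = 0.494). The turn of the cerebellar list follows from which libraries were removed, and these p-values take their spread from day 28 alone and the prior. Over the libraries left out, the median log2 fold change of thalamic and midbrain neuron genes ran from -0.46 to 0.0837, its value without day 28 replicate 1 (adjusted p = 0.55). With the replicate block limma called 0 genes (0 and 0), 2386 at an unadjusted p under 0.05, and 26 lists. Same-numbered samples correlated at 0.03, 0.13 and -0.06, and not every sample correlated best with its own number. No pairing by number was therefore detected. With so few libraries these correlations cannot exclude a batch shared by number, so the block result stands beside the main count. The planned count-model tests on recovered reads were not run. This was a choice made because the deposited unit is log2, although whole reads could be recovered. How many genes a count model would call is therefore not known. Genes under a mean of 10 normalized counts, where depth gives few reads, were tested only with no filter.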

Other observations

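The tests of the cerebellar, liver and midbrain explanations below, and that of 1 library for the interferon genes, were chosen after the result was seen. Of these, the tests of the cerebellar and midbrain explanations replaced 3 others, also written after the data were seen, that rested on a few chosen libraries, and the values of both are given. The tests on transcription factors and on unseen liver genes were written before those genes were looked at.

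Red blood cell genes had a median log2 difference of -0.93 over 8 members (adjusted p = 0.00216 with camera; adjusted p = 0.432 with an estimated correlation), with 0 past the threshold over all genes and 4 lower adjusted over the list alone. Leaving out day 3 replicate 2, the median log2 fold change of red blood cell genes was -0.59. Hbb-bs, an adult globin, stood at 1486 ± 617 and 712 ± 68.2 normalized counts (n = 3 each, limma adjusted p = 0.169), and reads shared between globin copies make it uncertain. Sparc, a matrix protein made by glia and vessels, fell by 1.05 (limma adjusted p = 0.0345). Vamp1, a synaptic vesicle protein, fell by 1.08 (limma adjusted p = 0.0479), in a list of perineuronal net and late-maturation genes with a median of -0.18 (adjusted p = 0.00344; adjusted p = 0.384 with an estimated correlation), of whose 19 members 1 fell over all genes and 6 were lower and 2 higher adjusted over the list alone. The median log2 fold change of perineuronal net and late-maturation genes was -0.10 without day 3 replicate 1 and -0.12 without day 28 replicate 1. The pituitary hormone genes Gh and Prl had 251 and 241 reads in day 28 replicate 3 and at most 7 in each other library, and Pomc had 256 reads in day 3 replicate 3 and at most 23 elsewhere.

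The hindbrain list and 2 of 19 thalamic and midbrain genes were lower at day 28 (adjusted p = 0.384 and 0.483 for these lists with an estimated correlation). Of 24 region-defining transcription factors not looked at before, 23 were lower, with a median log2 difference of -1.95, as a different share of brain regions in the tissue of each group predicts. Most lay near the floor: 14 were under the filter, 3 of them with reads in day 3 replicate 1 alone, while the 10 past it, of which Tlx3 and Lbx1 had reads in day 3 replicates 1 and 2 alone, were all lower (median -2.07). With the cerebellar value of each library as a covariate the hindbrain list had a median of -1.71, against -3.09 without it. Its mean difference with the covariate, -1.92, had a 95% interval from -3.77 to -0.08. The cerebellar value overlapped between the days, at -1.49 in day 3 replicate 3 and 0.26 in day 28 replicate 3, so it was not fully confounded with the day. With 6 libraries the interval was too wide to say how much of the hindbrain fall went with cerebellar tissue. The first test, of day 28 replicates 1 and 2 against day 3 replicate 3 alone, gave -4.38 for Slc6a3, En1, Slc18a2 and Irx3. These genes were picked among the largest falls in the same libraries, so a low value was fixed in advance. A true change with time after implantation or with age stays open and untested.

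The glucocorticoid-responsive list was lower at day 28, with 6 of 18 members past the threshold (adjusted p = 0.306 with an estimated correlation). Cerebellar tissue and liver transcripts were argued against as the whole source by the list's mean: with the cerebellar covariate the median was -0.996 and the mean -1.10 (95% interval -1.77 to -0.43), and without day 3 replicate 2, the library with liver transcripts, the median was -0.88 and the mean -1.07 (-1.42 to -0.73). A different share of midbrain cannot be told apart from the day. The mean of Slc6a3, Slc18a2 and En1 left a gap of 4.20 log2 units between the days. These genes were picked among called genes whose groups did not overlap, so a gap above 0 was fixed in advance and decides nothing. The first test of a midbrain share, on the called genes, gave 0.24 for day 3 replicate 3 minus replicate 1. That of cerebellar tissue, day 28 replicates 1 and 2 minus day 3 replicate 3, gave -0.97. Each rested on a few chosen libraries. Recovery from surgery or handling is a candidate explanation that was not tested, as no unimplanted mice were used here.

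Single day 3 libraries carried other signals. Without day 3 replicate 1 the interferon median went from -1.24 to -0.26. That library was picked for its high value, so this restates it, and a response at day 3 cannot be told apart from 1 unusual library. In day 3 replicate 2, 17 liver genes not looked at before had a median log2 excess of 6.13 over the other 5 libraries, 16 of them over 1, as liver tissue or RNA in that library predicts; brain also expresses Vtn and Itih3. Over all 25 liver genes the other libraries held a median of 0.0325% (day 3 replicate 1) to 1.77% (day 28 replicate 1) of its level. Whether that low level came from blood, dissection or reads passed between pooled libraries was not tested.

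Of the 10 splits of the 6 libraries into 3 and 3, only the real split, 1 of 10, gave as many as 31 genes (highest other 2) or 26 lists (highest other 19). With 10 splits no share under 0.1 is possible.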
